A study of Mus musculus with 12 samples.

How the data were processed

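Whole jejunum, a middle stretch of the small intestine, was profiled from wild-type (WT) mice and from mice with an inducible knockout (KO) of Fgfr1op, a centrosome gene whose current symbol is Cep43. Samples were taken at 6, 9 and 12 days after the start of the time scale that the labels call post-tamoxifen. Each of the 6 groups (2 genotypes at 3 days) held 2 mice, so there were 12 arrays. Per the labels' protocols, tamoxifen was given by injection into the abdomen at 75 mg per kg of body weight on 5 successive days. RNA came from whole tissue, so epithelium, muscle, connective tissue and immune cells all contributed to each value. The driver of the recombinase and the deleted part of the gene are not given in the sources used here, nor is it stated whether the WT mice received tamoxifen, were littermates or carried the recombinase.

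Biotin-labelled RNA was hybridised to the Affymetrix Mouse Gene 1.0 ST array, a one-colour array with one value per probe set, per the labels' protocols. The authors deposited log2 signal values for 35556 probe sets on 12 arrays, and these values were used as deposited. They ran from 2.29 to 14.13, with array medians between 5.95 and 6.02 and no missing value. The submitters' processing notes name limma and R 3.5, with no role for either; the methods of background correction, summarisation and normalisation are not given in the sources used here.

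Probe sets were named through the platform's annotation table. Of the 35556 probe sets, 21789 carried exactly 1 gene symbol, 1621 carried several and 12146 are unnamed here. Only those with 1 symbol were named or tested as genes. For the 999 symbols with more than 1 probe set, the probe set with the highest mean over the 12 arrays was used, which left 19938 genes. No low-signal filter was applied. No 2 arrays held identical values. The 2 arrays of a group correlated at 0.992 to 0.997 across genes.

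Differences were fitted with limma 3.58.1 in R 4.3.3 as a mean per group over all 12 arrays, with empirical Bayes moderation (6 residual and 5.23 prior degrees of freedom). KO was compared with WT at each day and averaged over days. The genotype by day interaction and the change over days within each genotype were tested with moderated F tests. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 19938 genes. A gene was called at an adjusted p under 0.05. The spread was shared by all groups because a group held only 2 mice. An exact permutation test of 2 mice against 2 cannot give a p below 0.333, so a single day has no exact test of its own. No signal depth is counted on an array, so the number of arrays limits the precision. The median standard error (SE) of a difference at 1 day was 0.12 on the log2 scale, and that of the average over days was 0.07. The labels say that each group had 2 mice but name no litter, cage or array batch.

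A total of 37 gene lists for intestinal cell types, epithelial functions, stress responses, immune responses and possible neighbouring tissues was fixed before the data were examined, as were the rule for named genes, the tests and most of the alternatives. Of 801 list entries, 719 had a probe set of their own, with 4 to 31 per list. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 148 tests (37 lists in 4 comparisons). Each list test was repeated with a correlation estimated from the residuals and with fry, which tests whether the genes of a list move, on balance, one way. Members are counted after adjustment over all genes and adjusted over the list alone. Lists were also tested for the day differences (111 tests) and for the changes over days in WT (74 tests).

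The genes named were the targeted gene, then per day the 8 largest rises and 8 largest falls among called genes whose 2 KO arrays both lay on the same side of both WT arrays. For the average over days, 6 were named per direction among genes lying on the same side at all 3 days. The 6 genes with the smallest p were named for the interaction, and the 4 with the smallest p for the change over days in each genotype. Where fewer than 5 genes passed, the 5 with the smallest p were named. For lists, the rule fixed beforehand named the 3 members past the threshold with the largest changes; the text gives 1 to 5 examples, mostly from these, and adds well-known markers and members that moved against their list, which were chosen after their values were seen. Predicted genes, unnamed clones, small RNAs and odorant receptor genes were skipped. At day 6 this skipped 3 called genes, of which 1 lay beyond the last fall named.

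The fit was tested on simulated data built from the real gene means and spreads, in 5 runs of 19938 genes. For KO against WT at 1 day, 57.0% of genes changed 1.5-fold, 90.8% of those changed 2-fold and 100% of those changed 4-fold were called, and 5.5% of the calls were false. For the average over days the values were 90.1%, 99.2% and 100%, with 5.0% of the calls false. For KO against WT at day 6, a list shifted by 0.4 was called in 5 of 5 runs, and 0 of 180 tests of unshifted lists were called; simulated genes varied independently of each other, unlike the genes of a tissue.

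Alternatives covered the choice of probe set per gene, all probe sets, a filter on dim genes (13956 genes above a mean of 5.30), quantile normalisation, median centring, an intensity trend with a robust prior, array weights, arrays of a single day, the replicate number as a block, each array left out in turn, a fold threshold of 1.5, an adjusted p of 0.10, and the estimated correlation and fry for lists. The mean of the smooth muscle list or of the B and plasma cell list per array was added as a covariate after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6. No genome coordinates were used here.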

Results

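The series asks how loss of a centrosomal gene alters the intestine, with a stated interest in the stem cells of the gut and in susceptibility to Crohn's disease. The data were 12 expression arrays of whole jejunum, 1 per mouse: 2 WT and 2 KO mice at each of days 6, 9 and 12 on the time scale that the labels call post-tamoxifen. The labels do not state whether the WT mice were injected, were littermates or carried the recombinase. Effects of the drug or the recombinase are therefore not separated here from those of gene loss in any difference between KO and WT. Along the first principal component, which held 60.1% of the variance, the 6 WT arrays lay between -27.6 and -22.1 and the KO arrays of day 6 at -11.1 and -11.9. The KO arrays of days 9 and 12 lay at 42.5, 37.7, 53.7 and 42.8.

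Cep43 (Fgfr1op), the targeted gene, had log2 signals of 6.97 and 6.90 in WT and 6.69 and 6.56 in KO at day 6. The signals were 6.96 and 7.05 in WT and 6.60 and 6.63 in KO at day 9, and 6.83 and 7.04 in WT and 6.97 and 6.74 in KO at day 12. KO was lower by a log2 difference of -0.39 (SE 0.11, n = 2 per genotype, limma adjusted p = 0.0184) at day 9. The difference did not pass at day 6 (-0.31, SE 0.11, adjusted p = 0.267) or at day 12 (-0.09, SE 0.11, adjusted p = 0.638). Averaged over days, Cep43 fell by 0.26 in KO (SE 0.06, 6 mice per genotype, limma adjusted p = 0.00713), and an exact permutation test within days gave p = 0.0185, the smallest it can give being 0.00926. The day 9 call ended without any single array of that day, with differences of -0.38 and -0.41 without KO replicates 1 and 2 and of -0.44 and -0.35 without WT replicates 1 and 2. At day 12 the difference was -0.20 without KO replicate 1 and 0.03 without KO replicate 2. The probe set may cover exons outside the deleted part, and cells that kept the gene are part of the tissue, so this signal checks the labels only weakly.

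**Figure D1:**
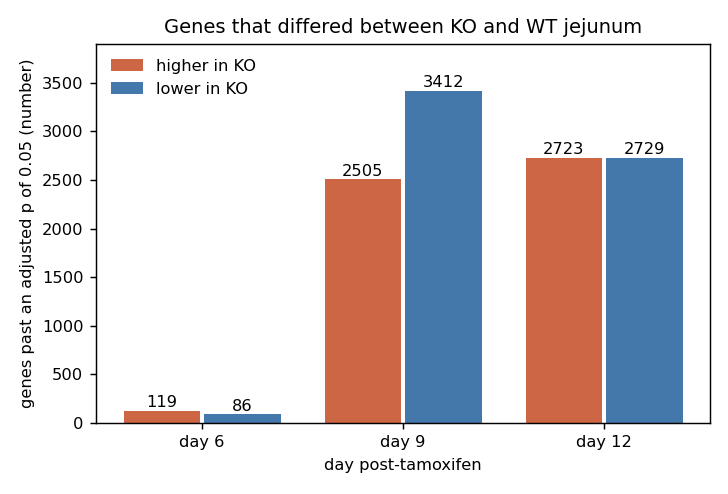
Number of genes past a limma adjusted p of 0.05 for KO against WT jejunum (y axis) by day after tamoxifen, 6 to 12 (x axis), split into genes higher (orange) and lower (blue) in KO, with 2 mice per genotype and day. The bars stand at 119 and 86 genes at day 6, 2505 and 3412 at day 9, and 2723 and 2729 at day 12.

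Day 6 asked what differed soon after tamoxifen. Mboat1, a lysophospholipid acyltransferase, was 5.30-fold higher in KO than in WT (SE 0.14 on the log2 scale, adjusted p = 5.56e-05), and Nox1, a superoxide-producing NADPH oxidase of the epithelium, was 3.12-fold higher (log2 1.64, SE 0.13). Ankrd22, an ankyrin repeat protein, and Dusp8, a phosphatase of MAP kinases, were higher by log2 differences of 1.88 (SE 0.13) and 1.79 (SE 0.13). Apol10a, of the apolipoprotein L family, was 8.86-fold lower (log2 -3.15, SE 0.28, adjusted p = 5.34e-04), and Reg3a, an antimicrobial lectin of the Reg3 multigene family, was 3.64-fold lower (SE 0.19 on the log2 scale). Further rises were those of Igkv4-91 (log2 4.15, SE 0.61), a variable segment of the immunoglobulin multigene family, Fhdc1 (1.55), the aldo-keto reductase Akr1b8 (1.49) and the membrane-anchored Gml (1.46). Further falls were those of the complement inhibitor Cd59a (-2.88), the vitamin B12 uptake receptor Cubn (-1.88), the gasdermins Gsdmc4 (-1.86) and Gsdmc2 (-1.64), the muscle heat shock protein Hspb6 (-1.67) and the muscarinic receptor Chrm2 (-1.51). The mean of Gsdmc4 in KO was 4.96, a signal not tested against background.

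In all, 205 of 19938 genes passed at day 6 with limma, 119 higher and 86 lower, that is 58.0% higher. This share depended on the scaling: with arrays centred on their medians 155 of 227 were higher, or 68.3%, and with quantile normalisation 90 of 174, or 51.7%. The calls of Mboat1, Ankrd22, Dusp8, Nox1, Apol10a and Reg3a held with any 1 array left out. Of the 16 genes named, 9 lost their call without KO day 6 replicate 2, 8 without WT replicate 1, 7 without KO replicate 1 and 4 without WT replicate 2 of that day. The calls of Cubn, Hspb6 and Chrm2 also ended without either WT array of day 12, those of Cubn and Chrm2 without either WT array of day 9, and that of Cubn without either KO array of day 9. Over all arrays left out, log2 differences ran from 3.39 to 4.91 for Igkv4-91, 1.26 to 1.84 for Fhdc1, 1.42 to 1.56 for Akr1b8 and 1.29 to 1.63 for Gml. They ran from -3.32 to -2.44 for Cd59a, -2.19 to -1.58 for Cubn, -2.42 to -1.29 for Gsdmc4, -1.93 to -1.41 for Hspb6, -1.69 to -1.59 for Gsdmc2 and -1.89 to -1.13 for Chrm2. The count was 21 without KO day 6 replicate 2, 29 without KO replicate 1, 40 without WT replicate 1 and 136 without WT replicate 2 of that day. It was 96 without either WT array of day 9, and 113 without either WT array of day 12.

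Among gene lists at day 6, members with roles in mitosis stood higher in KO. Of 31 measured members, 2 rose, the spindle midzone protein Prc1 (log2 0.66, SE 0.13) and the cytokinesis protein Anln (0.49, SE 0.09), and 29 did not pass; 10 rose when adjusted over the list alone (median 0.29, camera adjusted p = 7.68e-13, and adjusted p = 0.338 with an estimated correlation). The proliferation marker Mki67 stood at 0.02 (SE 0.23). Of 30 members of the DNA replication list, 0 passed over all genes or adjusted over the list alone, with Mcm5 at 0.41 (SE 0.11). The median was 0.22 (adjusted p = 1.64e-06, and adjusted p = 0.353 with an estimated correlation). Of 26 interferon-stimulated genes 5 rose and 21 did not pass, and 11 rose when adjusted over the list alone (median 0.39, adjusted p = 2.17e-10, and adjusted p = 0.338 with an estimated correlation). They were the ISG15 protease Usp18 (1.36, SE 0.26), the antiviral Rsad2 (1.12, SE 0.15), and Oasl2 (1.21), Oas3 (1.10) and Oasl1 (0.55) of the oligoadenylate synthetase family. Of 22 targets of p53, the DNA damage response factor, 4 rose and 18 did not pass, and 7 rose when adjusted over the list alone: the kinase Plk2 (0.95, SE 0.15), the cyclin Ccng1 (0.73, SE 0.10), the stress protein Sesn2 (0.70, SE 0.11) and the receptor Eda2r (0.60, SE 0.12). The median was 0.12 (adjusted p = 1.67e-05, and adjusted p = 0.163 with an estimated correlation).

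Smooth muscle genes stood lower in KO at day 6. Of 15 members, Hspb6 fell (log2 -1.67, SE 0.32) and 14 did not pass, while 14 fell when adjusted over the list alone; the intermediate filament Des stood at -2.19 (SE 0.47) and the muscle actin Actg2 at -2.01 (SE 0.48). The list median was -1.33 (adjusted p = 8.74e-15, and adjusted p = 0.338 with an estimated correlation). The list mean per array, relative to its mean over all WT arrays, was 0.56 and -0.08 in WT and -0.91 and -1.05 in KO. The smooth muscle signal thus differed between genotypes at day 6 beside every list above. With that mean as a covariate 17 genes passed in place of 205. The list of fatty acid oxidation had a median of -0.25 in 19 members, with a fall of Decr1 (-0.56, SE 0.10) and 4 falls when adjusted over the list alone (adjusted p = 2.43e-07, and adjusted p = 0.338 with an estimated correlation). Of 19 intestinal stem cell markers, the adhesion receptor Cd44 rose (0.87, SE 0.10), 18 did not pass, and 1 rose and 3 fell when adjusted over the list alone (median -0.27, adjusted p = 0.00516, and adjusted p = 0.338 with an estimated correlation); Olfm4 stood at -0.51 (adjusted p = 0.209).

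Camera called 8 further lists at day 6. The junction list (25 members, median 0.17, adjusted p = 2.44e-04, and adjusted p = 0.353 with an estimated correlation) held a rise of the pore-forming claudin Cldn2 (0.83, SE 0.16), with 4 rises when adjusted over the list alone. The integrated stress list (21 members, median 0.12, adjusted p = 0.00267, and adjusted p = 0.366 with an estimated correlation) held rises of Chac1 (0.82) and Trib3 (0.78), with 5 when adjusted over the list alone. The centriole and centrosome list, the family of the targeted gene, had a median of 0.08 in 28 members, with a rise of the abscission protein Cep55 (0.78, SE 0.12) and 2 rises when adjusted over the list alone (adjusted p = 0.0202, and adjusted p = 0.483 with an estimated correlation). Medians were 0.14 for 18 cholesterol synthesis genes (adjusted p = 0.0246, and adjusted p = 0.681 with an estimated correlation) and 0.09 for 17 fetal-like and YAP target genes (adjusted p = 0.0464, and adjusted p = 0.366 with an estimated correlation). They were -0.14 for 20 tuft cell genes (adjusted p = 0.0102, and adjusted p = 0.338 with an estimated correlation), -0.11 for 16 enteric neuron and glia genes (adjusted p = 0.0203, and adjusted p = 0.353 with an estimated correlation) and -0.36 for 16 B and plasma cell genes (adjusted p = 0.0254, and adjusted p = 0.655 with an estimated correlation). In these last 5 lists 0 members passed over all genes, and adjusted over the list alone 4 rose in the fetal-like list and 0 in the others. Calls ended without KO day 6 replicate 1 (fetal-like, adjusted p = 0.138; B and plasma cell, 0.479; enteric neuron, 0.0520), KO replicate 2 (centriole, 0.143; cholesterol, 0.0506), WT replicate 1 (cholesterol, 0.819; enteric neuron, 0.476), WT replicate 2 (centriole, 0.176; tuft cell, 0.0782; fetal-like, 0.351; B and plasma cell, 0.723 with its direction turned), and KO day 9 replicates 1 and 2 (fetal-like, 0.0750 and 0.0779). The medians of the goblet cell, enteroendocrine, brush border, mast cell and fibroblast lists, 0 of them called, differed in sign from their means or tests.

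By day 9 the absorptive programme of the epithelium was lower in KO. Slc34a2, a sodium phosphate cotransporter, was lower by a log2 difference of -6.77 (SE 0.20, n = 2 per genotype, limma adjusted p = 5.01e-09), and Lct, the lactase of the brush border, was 48.0-fold lower (log2 -5.59, SE 0.19). Olfm4, a secreted marker of intestinal stem cells, was 27.9-fold lower (log2 -4.80, SE 0.16). Apol10a (log2 -5.94), the glucuronosyltransferase Ugt2a3 (-5.86), the intestinal sphingomyelinase Enpp7 (-5.25), the aspartoacylase Aspa (-4.92) and the alcohol dehydrogenase Adh6a (-4.84) fell too. Anxa10, an annexin, was higher by a log2 difference of 5.79 (SE 0.15, adjusted p = 2.28e-09). Sprr1a, a cornified envelope protein, was 19.5-fold higher (log2 4.28, SE 0.35), and Slc40a1, the iron exporter ferroportin, 13.5-fold higher (log2 3.76, SE 0.15). Log2 rises were 4.03 for Fam162a, a mitochondrial protein, 4.03 for Gml, 3.79 for the bile acid transporter Slc10a2 and 3.63 for Mboat1, and the log2 rise of the cystine transporter Slc7a11 was 3.81. Limma called 5917 of 19938 genes, 2505 higher and 3412 lower, shares against which the counts of list members at this day have to be read. The 42.3% that were higher became 48.8% with quantile normalisation (2862 of 5865) and 38.1% with arrays centred on their medians (2194 of 5754). Falls thus outnumbered rises under each of these scalings, while the size of the excess depended on the scaling. At 1.5-fold or more, 938 genes were higher and 1892 lower with the deposited values. No fold is given where a group mean lay under 5.30, as for Anxa10 in WT (4.28) and for Slc34a2 (4.96) and Ugt2a3 (4.89) in KO, since signals were not tested against background. The log2 differences of such genes are differences of signal, whose size and rank need not be those of the RNA. Each of these 16 named calls held with any 1 array left out, while the count was 3646 without WT day 9 replicate 2 and 3889 without KO day 9 replicate 1.

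Of 27 brush border genes, 21 fell, 0 rose and 6 did not pass at day 9, and 22 fell when adjusted over the list alone (median -0.93, adjusted p = 2.04e-13, and adjusted p = 0.338 with an estimated correlation); the metalloprotease Mep1a (-4.02, SE 0.25) and the sodium-proton exchanger Slc9a3 (-2.74, SE 0.33) fell. Of 22 genes of lipid absorption 13 fell and 2 rose (14 and 2 when adjusted over the list alone), among them the fatty acid receptor Cd36 (-1.85, SE 0.23) and the cholesterol transporter Npc1l1 (-1.68, SE 0.13). The median was -0.46 (adjusted p = 8.12e-05, and adjusted p = 0.353 with an estimated correlation). Of 19 genes of fatty acid oxidation 12 fell and 1 rose (12 and 1 when adjusted over the list alone). The median was -0.79 (adjusted p = 5.56e-06, and adjusted p = 0.338 with an estimated correlation). Hadh (-2.38, SE 0.11) and Ehhadh (-2.02, SE 0.10) fell, and Acadl, the long-chain acyl-CoA dehydrogenase, rose (1.44, SE 0.16). Of 27 genes of xenobiotic metabolism 16 fell and 3 rose (16 and 3 when adjusted over the list alone): the cytochrome P450 Cyp2b10 fell (-4.77, SE 0.26) and the glutathione transferase Gsta4 rose (3.02, SE 0.20). The median was -0.80 (adjusted p = 3.54e-05, and adjusted p = 0.453 with an estimated correlation).

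Of 19 stem cell markers 10 fell, 4 rose and 5 did not pass at day 9 (10 and 4 when adjusted over the list alone). The median was -0.41 (adjusted p = 0.0219, and adjusted p = 0.353 with an estimated correlation). Lgr5, the receptor that marks crypt base stem cells, fell by 1.56 (SE 0.16) with Olfm4, while Cd44 (1.53, SE 0.10) and the growth factor binding protein Igfbp4 (1.37, SE 0.25) rose. Of 17 fetal-like and YAP target genes, a set linked to regenerating and fetal gut epithelium, 12 rose and 0 fell (13 when adjusted over the list alone). The median was 1.36 (adjusted p = 1.54e-07, and adjusted p = 0.163 with an estimated correlation). Examples were the calcium-binding S100a6 (2.67, SE 0.18), the interleukin 1 receptor antagonist Il1rn (2.61, SE 0.14), the annexin Anxa3 (2.31, SE 0.11) and clusterin, Clu (2.31, SE 0.66). Of 30 DNA replication genes 8 fell and 0 rose, also when adjusted over the list alone (median -0.19, adjusted p = 0.0200, and adjusted p = 0.613 with an estimated correlation), with Rfc4 (-0.94, SE 0.13) and the primase Prim1 (-0.76, SE 0.14). Fry did not call that list (adjusted p = 0.0562). Of 20 tuft cell genes 7 fell and 0 rose, also when adjusted over the list alone (median -0.15, adjusted p = 0.0343, and adjusted p = 0.353 with an estimated correlation), with the signalling regulator Rgs13 (-1.83, SE 0.19) and the kinase Dclk1 (-0.83, SE 0.12). The DNA replication call ended without KO day 9 replicate 2 (adjusted p = 0.179) or WT replicate 1 (0.101), and the tuft cell call without KO replicate 2 (0.0822) or WT replicate 2 (0.0769). With the filter on dim genes the stem cell, DNA replication and tuft cell calls ended. Of 22 p53 targets 5 rose, among them Plk2 (0.63, SE 0.15), and 5 fell, among them Fas (-1.42, SE 0.14), with 8 and 6 when adjusted over the list alone. The p53 list was called by neither camera nor fry (median -0.01, adjusted p = 0.967 and 0.195). From day 6 to day 9 its KO minus WT difference moved down by a median of -0.24 (camera adjusted p = 0.0323, and adjusted p = 0.357 with an estimated correlation; fry adjusted p = 0.00216). The mitosis list was called by neither camera nor fry (median -0.07, camera adjusted p = 0.527, 3 rose and 5 fell of 31).

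Genes of immune surveillance were lower in KO at day 9. Of 12 antigen presentation genes, 4 of them in the MHC multigene family, 10 fell and 1 rose (11 and 1 when adjusted over the list alone): the peptide transporter Tap1 (-1.57, SE 0.21) and the class II chain H2-Aa (-1.39, SE 0.19) fell, and the class I transactivator Nlrc5 rose (0.51, SE 0.15). The median was -1.04 (adjusted p = 2.24e-05, and adjusted p = 0.358 with an estimated correlation). Of 26 interferon-stimulated genes 13 fell and 0 rose (16 when adjusted over the list alone), with the GTPase Irgm1 (-1.97, SE 0.22) and Ifit1 (-1.79, SE 0.30). The median was -0.50 (adjusted p = 1.78e-04, and adjusted p = 0.456 with an estimated correlation). Of 20 markers of T cells and intraepithelial lymphocytes 10 fell and 0 rose (11 when adjusted over the list alone), with the granzymes Gzmb (-2.09, SE 0.28) and Gzma (-1.56, SE 0.29). The median was -0.57 (adjusted p = 2.69e-04, and adjusted p = 0.456 with an estimated correlation). The WT mice rose between days 6 and 9, by median log2 differences of 0.95 for antigen presentation, 0.30 for interferon-stimulated genes and 0.27 for T cell markers. The antigen presentation mean, relative to all WT arrays, went from -0.544 and -0.247 to 0.598 and 0.259 in WT. In KO it was -0.645 and -0.322 at day 6 and -0.47 and -0.579 at day 9. The day 9 difference of that list thus came with a rise in WT and no clear fall in KO. The KO means of the interferon and T cell lists were lower at day 9 than at day 6. Camera called all 3 of these lists between the WT days (adjusted p = 8.36e-14, 8.07e-11 and 6.14e-06), though not with an estimated correlation (adjusted p = 0.539, 0.539 and 0.630). Of 18 death effector genes 8 fell and 1 rose (10 and 2 when adjusted over the list alone): Tnfsf10, the death ligand TRAIL, was 18.4-fold lower (SE 0.14 on the log2 scale), and the inhibitor of caspase 8 Cflar fell (-0.98, SE 0.14), while the necroptosis kinase Ripk3 rose (1.00, SE 0.19). The median was -0.32 (adjusted p = 0.00536, and adjusted p = 0.353 with an estimated correlation).

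Besides the fetal-like list, lists that stood higher at day 9 were those of contractile, stress, neutrophil and stromal genes. Of 26 actomyosin genes 10 rose and 3 fell, also when adjusted over the list alone (median 0.35, adjusted p = 0.00481, and adjusted p = 0.373 with an estimated correlation), with the myosin light chain Myl6 (1.70, SE 0.21) and the small GTPase Rhoc (1.66, SE 0.11). Of 21 integrated stress genes 9 rose and 1 fell, also when adjusted over the list alone (median 0.18, adjusted p = 0.00289, and adjusted p = 0.368 with an estimated correlation), with the asparagine synthetase Asns (1.69, SE 0.18) and the transcription factor Atf5 (1.47, SE 0.15). Of 16 neutrophil genes 6 rose and 0 fell (9 when adjusted over the list alone), with Retnlg (1.15, SE 0.23) and S100a8 (0.69, SE 0.11). The median was 0.36 (adjusted p = 0.00291, and adjusted p = 0.338 with an estimated correlation). Of 22 fibroblast and matrix genes 10 rose and 2 fell (11 and 2 when adjusted over the list alone), with the metalloprotease Mmp3 (1.49, SE 0.19) rising and Fbln1 (-0.96, SE 0.10) falling. The median was 0.45 (adjusted p = 0.0196, and adjusted p = 0.655 with an estimated correlation), and fry did not call the list (adjusted p = 0.0853). Of 12 visceral fat and mesothelium genes 5 rose, also when adjusted over the list alone (median 0.34, adjusted p = 0.00469, and adjusted p = 0.410 with an estimated correlation), led by the lipoprotein lipase Lpl (0.99, SE 0.12); another was Krt19 (0.37, SE 0.10), a keratin that gut epithelium also makes. The fibroblast call ended without WT day 9 replicate 1 (adjusted p = 0.123) and the visceral fat call without KO day 9 replicate 1 (0.0597). With the filter on dim genes the neutrophil and fibroblast calls ended. Among lists not called by camera, the median differed in sign from the mean or the test in those of NF-kB, B and plasma cell, smooth muscle, endothelium, junction, Crohn's disease risk, erythrocyte, pancreatic acinar and liver genes.

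At day 12 Anxa10, with a mean log2 signal of 4.31 in WT, not tested against background, was higher in KO by a log2 difference of 7.47 (SE 0.15, n = 2 per genotype, limma adjusted p = 3.96e-10). Fezf1, a transcription factor of the developing forebrain with a mean of 5.29 in WT, was higher by 5.98 (SE 0.19), with a log2 difference of 0.51 at day 9. Slc7a11 (4.84), Slc40a1 (4.73), the secreted Wfdc18 (4.45), Sprr1a (4.34), the mucin-like Mucl3 (4.16) and the phospholipid scramblase Plscr4 (4.12) were also higher, with SEs from 0.15 to 0.36 on the log2 scale. The WT means of Wfdc18 (4.84) and Mucl3 (4.34), and below the KO means of Spink1 (4.74) and Slc34a2 (4.94), lay under 5.30 too, so the size and rank of these differences are those of signal only. Olfm4 was 97.4-fold lower (log2 -6.61, SE 0.16, adjusted p = 5.85e-10), Enpp7 89.8-fold lower (SE 0.26) and Lct 79.9-fold lower (SE 0.19). Further log2 falls were those of the histamine-degrading Aoc1 (-5.95), the trypsin inhibitor Spink1 (-5.67), the lactate transporter Slc5a12 (-5.45), Slc34a2 (-5.31) and the peptidase Naaladl1 (-5.27). Limma called 5452 of 19938 genes, 2723 higher and 2729 lower, shares against which the counts of list members at this day have to be read. The 49.9% that were higher became 50.6% with quantile normalisation and 52.2% with arrays centred on their medians. Each of these 16 named calls held with any 1 array left out.

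Dividing-cell genes were lower in KO at day 12. Of 31 mitosis genes 27 fell, 0 rose and 4 did not pass (28 fell when adjusted over the list alone), with the spindle protein Nusap1 (-1.72, SE 0.16), the topoisomerase Top2a (-1.68, SE 0.12) and Mki67 (-1.62, SE 0.23). The median was -0.87 (adjusted p = 9.58e-15, and adjusted p = 0.338 with an estimated correlation). Of 30 DNA replication genes 22 fell and 0 rose (25 when adjusted over the list alone), with Prim1 (-1.53, SE 0.14) and the helicase subunit Mcm6 (-1.18, SE 0.10). The median was -0.74 (adjusted p = 2.15e-13, and adjusted p = 0.338 with an estimated correlation). Of 19 stem cell markers 10 fell and 3 rose (10 and 4 when adjusted over the list alone): Lgr5 (-2.13, SE 0.16) and the Wnt target Axin2 (-1.74, SE 0.14) fell with Olfm4, and Cd44 (1.85, SE 0.10), Sox9 (1.10, SE 0.16) and Msi1 (0.95, SE 0.10) rose. The median was -0.49 (adjusted p = 0.0126, and adjusted p = 0.353 with an estimated correlation). The centriole and centrosome list was called by neither camera nor fry (median -0.08, adjusted p = 0.451 and 0.412; 7 fell and 3 rose of 28). Sass6, a protein of the centriole cartwheel, fell (-1.04, SE 0.19), and Stil, its partner in centriole assembly, rose (1.00, SE 0.16). Camera did not call the p53 target list (median 0.32, adjusted p = 0.0667, and adjusted p = 0.338 with an estimated correlation), while fry called it higher (adjusted p = 4.95e-04). Of its 22 members 9 rose and 3 fell (12 and 3 when adjusted over the list alone), with Plk2 at 2.33 (SE 0.15) and the death receptor Fas at -0.97 (SE 0.14).

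Among absorptive functions at day 12, 22 of 27 brush border genes fell and 1 rose (24 and 1 when adjusted over the list alone). The median was -1.37 (adjusted p = 8.74e-15, and adjusted p = 0.338 with an estimated correlation). The peptidases Dpp4 (-3.48, SE 0.16) and Ace (-2.55, SE 0.15) fell, and the rise was that of the alkaline phosphatase Alpi (0.42, SE 0.11). Lipid absorption fell in 11 of 22 members and rose in 1 (13 and 1 when adjusted over the list alone), with the fatty acid binding protein Fabp1 at -2.41 (SE 0.10) and the desaturase Scd2 at 1.80 (SE 0.24). The median was -0.64 (adjusted p = 4.55e-06, and adjusted p = 0.338 with an estimated correlation). Fatty acid oxidation had 12 falls and 1 rise, that of Acadl (1.96, SE 0.16), among 19 members (13 and 1 when adjusted over the list alone). The median was -0.58 (adjusted p = 2.46e-05, and adjusted p = 0.338 with an estimated correlation). Xenobiotic metabolism had 14 falls and 4 rises among 27 members (16 and 5 when adjusted over the list alone), with the carboxylesterase Ces2a at -4.01 (SE 0.46) and Gsta4 at 3.13 (SE 0.20). The median was -0.68 (adjusted p = 1.41e-04, and adjusted p = 0.472 with an estimated correlation). Of 18 cholesterol synthesis genes 13 rose and 1 fell (15 and 1 when adjusted over the list alone). The median was 0.74 (adjusted p = 2.04e-05, and adjusted p = 0.410 with an estimated correlation). Hsd17b7 (1.97, SE 0.16), the squalene epoxidase Sqle (1.48, SE 0.18) and Cyp51 (1.35, SE 0.13) rose, and Dhcr7, which makes the last step to cholesterol, fell (-1.08, SE 0.20). In WT the same list had a median of -0.36 at day 12 against day 6 (adjusted p = 6.29e-11, and adjusted p = 0.539 with an estimated correlation).

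Of 17 fetal-like and YAP target genes 13 rose and 1 fell at day 12, also when adjusted over the list alone (median 1.46, adjusted p = 1.69e-07, and adjusted p = 0.163 with an estimated correlation). Il1rn (3.88, SE 0.14), S100a6 (3.17, SE 0.18) and the annexin Anxa1 (2.77, SE 0.18) rose, while the alarmin Il33 fell (-0.93, SE 0.25) after a rise of 1.36 (SE 0.25) at day 9. Of 26 actomyosin genes 10 rose and 2 fell (12 and 3 when adjusted over the list alone), with Rhoc (1.55, SE 0.11) and the actin crosslinker Actn1 (2.83-fold, SE 0.10 on the log2 scale). The median was 0.36 (adjusted p = 0.00262, and adjusted p = 0.353 with an estimated correlation). Of 10 Paneth cell genes 7 fell and 1 rose (8 and 1 when adjusted over the list alone): Habp2 (-1.94, SE 0.19) and the antimicrobial Ang4 (-1.49, SE 0.19) fell, and the lipase Pnliprp2 rose (1.17, SE 0.19). The median was -0.76 (adjusted p = 0.00142, and adjusted p = 0.410 with an estimated correlation). Of 20 tuft cell genes 12 fell and 1 rose, also when adjusted over the list alone (median -0.44, adjusted p = 1.07e-04, and adjusted p = 0.338 with an estimated correlation), with Rgs13 (-2.94, SE 0.19) and Dclk1 (-1.20, SE 0.12) falling and the actin regulator Avil (0.73, SE 0.13) rising. Of 22 enteroendocrine genes 6 fell and 2 rose (7 and 2 when adjusted over the list alone): the hormones neurotensin, Nts (-2.64, SE 0.19), and Gip (-1.27, SE 0.13) fell, and the transcription factors Neurod1 (0.78, SE 0.12) and Insm1 (0.33, SE 0.10) rose. The median was -0.17 (adjusted p = 0.0372, and adjusted p = 0.353 with an estimated correlation). The enteroendocrine call ended without KO day 12 replicate 2 (adjusted p = 0.170), and also with the filter on dim genes. Of 21 integrated stress genes 10 rose and 6 fell, also when adjusted over the list alone, with the lipoprotein receptor Vldlr (3.77, SE 0.14) rising. Camera did not call that list (median 0.21, adjusted p = 0.214), while fry called it higher (adjusted p = 0.00777). Goblet cell genes were called by neither camera nor fry (median 0.12, mean -0.04, camera adjusted p = 0.999; 5 rose and 4 fell of 17).

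**Figure D2:**
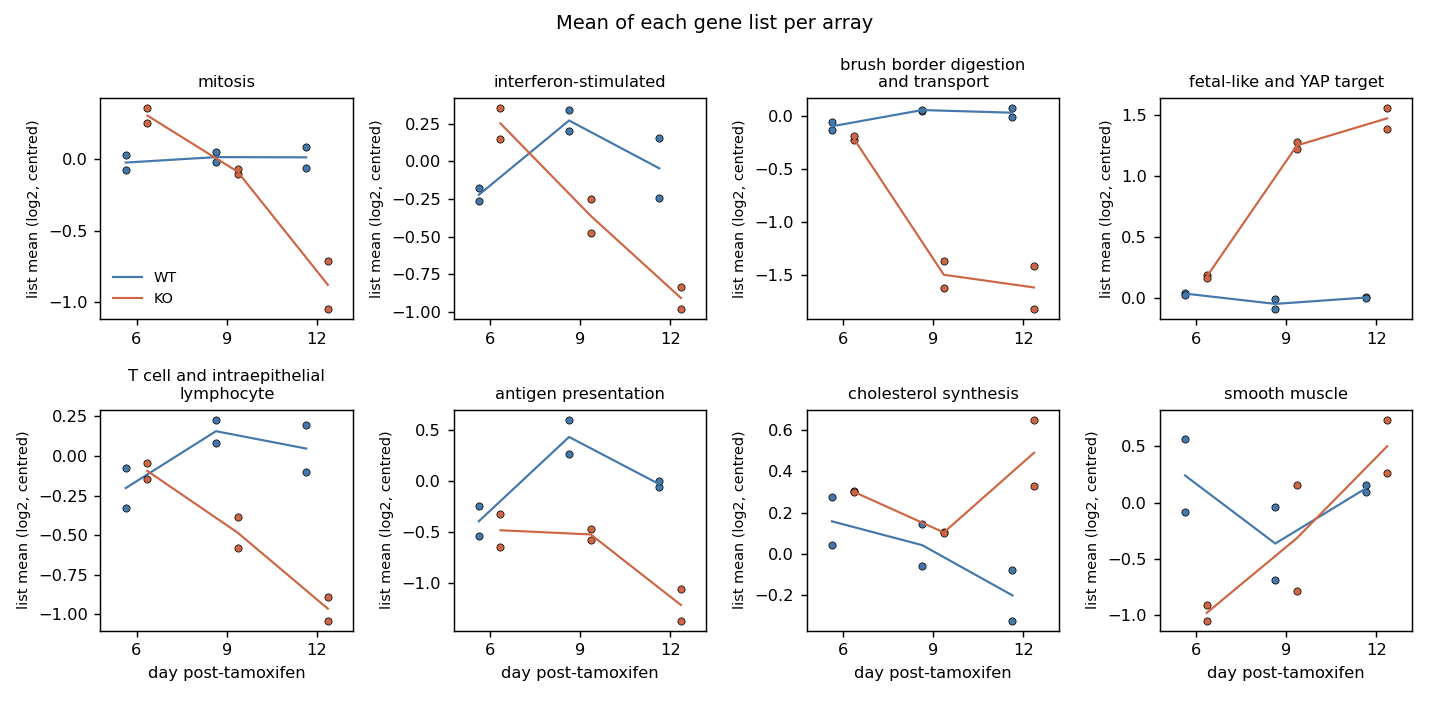
Mean log2 signal of 8 gene lists minus its mean over all WT arrays (y axis), per array by day after tamoxifen, 6 to 12 (x axis). Points are single mice (2 per genotype and day), lines join group means, blue is WT and orange is KO. The smooth muscle means are -0.91 and -1.05 in KO and 0.56 and -0.08 in WT at day 6, and the interferon-stimulated means are -0.83 and -0.98 in KO at day 12.

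Immune cell lists moved in both directions at day 12. Of 20 T cell and intraepithelial lymphocyte markers 15 fell and 0 rose (18 when adjusted over the list alone), with Gzma (-2.68, SE 0.29), Gzmb (-2.28, SE 0.28) and the receptor chain Cd3g (-2.10, SE 0.17). The median was -0.91 (adjusted p = 1.61e-09, and adjusted p = 0.338 with an estimated correlation). Of 16 B and plasma cell genes 5 fell and 0 rose, also when adjusted over the list alone (median -0.86, adjusted p = 6.19e-04, and adjusted p = 0.456 with an estimated correlation), with the antibody joining chain Jchain (-1.46, SE 0.18); the list mean differed between the 2 WT mice of that day (-0.35 and 0.64), and fry did not call the list (adjusted p = 0.0833). Antigen presentation fell in 11 of 12 genes, also when adjusted over the list alone (median -1.16, adjusted p = 1.69e-07, and adjusted p = 0.338 with an estimated correlation), with the immunoproteasome subunits Psmb8 (-2.10, SE 0.25) and Psmb9 (-1.82, SE 0.18). Of 26 interferon-stimulated genes 15 fell and 0 rose (18 when adjusted over the list alone), with Ifit1 (-2.39, SE 0.30), the chemokine Cxcl9 (-2.18, SE 0.31) and the RNA sensor Ddx58 (-1.92, SE 0.10). The median was -0.81 (adjusted p = 1.56e-07, and adjusted p = 0.353 with an estimated correlation). Of 16 macrophage and monocyte genes 9 rose and 2 fell (10 and 2 when adjusted over the list alone): the scavenger receptors Cd163 (1.87, SE 0.13) and Mrc1 (1.03, SE 0.16) rose, and Lyz2 (-0.41, SE 0.12) and Adgre1 (-0.38, SE 0.12) fell. The median was 0.40 (adjusted p = 0.00727, and adjusted p = 0.338 with an estimated correlation). Of 16 neutrophil genes 4 rose and 0 fell, also when adjusted over the list alone (median 0.19, adjusted p = 0.00785, and adjusted p = 0.338 with an estimated correlation), with Retnlg (2.60, SE 0.23) and Ly6g (1.14, SE 0.23), while S100a9 stood at -0.05 (SE 0.11). Of 18 death effector genes 7 fell and 2 rose (7 and 3 when adjusted over the list alone), with Tnfsf10 (-3.75, SE 0.14) and the pyroptosis pore protein Gsdmd (-2.07, SE 0.17) falling. The median was -0.21 (adjusted p = 0.0236, and adjusted p = 0.410 with an estimated correlation). The visceral fat and mesothelium list had 4 rises of 12, also when adjusted over the list alone (median 0.31, adjusted p = 0.0203, and adjusted p = 0.483 with an estimated correlation), with Lpl (0.81, SE 0.12). The death effector and visceral fat calls ended without KO day 12 replicate 1 (adjusted p = 0.0610 and 0.0606). With the filter on dim genes the neutrophil and death effector calls ended.

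The Crohn's disease risk list, 25 genes near or in human risk loci, was not called by camera at any day, with adjusted p = 0.803, 0.826 and 0.0565 at days 6, 9 and 12. Fry called it lower at day 12 (adjusted p = 0.0201) and did not call it at day 6 (adjusted p = 0.741) or day 9 (adjusted p = 0.329). Camera called the list at day 12 with the mean of a gene's probe sets or either replicate block. It also called the list with the arrays of day 12 alone, there adjusted over 37 tests in place of 148. At day 12, 3 of its members rose and 8 fell (3 and 10 when adjusted over the list alone; median -0.27). Fut2, which adds fucose to mucosal glycans, rose by 2.99 (SE 0.33), the microbial lectin Itln1 fell by 1.26 (SE 0.15) and the autophagy GTPase Irgm1 fell by 1.02 (SE 0.22), whereas the bacterial sensor Nod2 stood at -0.11 (SE 0.11) and the autophagy gene Atg16l1 at 0.03 (SE 0.10). The 26 inflammatory cytokine and NF-kB genes were called by neither camera nor fry (camera adjusted p = 0.167, 0.949 and 0.375 at days 6, 9 and 12); the chemokine Ccl20 rose at day 12 (1.70, SE 0.45) and the feedback inhibitor Socs3 fell (-0.86, SE 0.13). Lists for tissue that a dissection might include were called by neither test at any of the 3 days for erythrocytes, pancreatic acinar cells or liver. In the pancreatic acinar list the colipase Clps fell at day 12 (-1.59, SE 0.25), and in the liver list Cps1, which enterocytes also make, fell (-1.74, SE 0.16). Among lists not called by camera at day 12, the median differed in sign from the mean or the test in those of goblet cell, antimicrobial, junction and liver genes.

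Averaged over the 3 days, 6493 genes passed with limma, 3121 higher and 3372 lower in KO (6 mice per genotype). The 48.1% that were higher became 51.5% with quantile normalisation (3413 of 6627) and 49.6% with arrays centred on their medians (3232 of 6515), so the direction of the excess depended on the scaling. Mboat1 (log2 3.24, SE 0.08), Gml (3.17, SE 0.11), Slc10a2 (2.84, SE 0.10) and Ankrd22 (2.72, SE 0.08) were higher at each day, as were Fam162a (2.67, SE 0.09) and the EGF receptor ligand Btc (2.65, SE 0.06, adjusted p = 1.09e-10). Apol10a (-4.75, SE 0.16), Slc34a2 (-4.39, SE 0.12), Lct (-4.33, SE 0.11), Olfm4 (-3.97, SE 0.09), Enpp7 (-3.95, SE 0.15) and Adh6a (-3.52, SE 0.12) were lower at each day, although the day 6 difference of Olfm4, Enpp7, Adh6a and Fam162a did not pass on its own. Each of these 12 calls held with any 1 array left out. Of the lists, 22 of 37 were called for the average, 8 higher and 14 lower. List means were also put to the exact permutation test within days, adjusted over the lists. The brush border, fetal-like and integrated stress lists passed it (adjusted p = 0.0381 each, the smallest reached). So did the stem cell, Paneth cell, tuft cell, lipid absorption, fatty acid oxidation and macrophage lists, at the same value. Every other list failed it. Among these were the B and plasma cell (adjusted p = 0.307), fibroblast (0.140) and visceral fat lists (0.137), which camera called. The antigen presentation, xenobiotic and neutrophil lists (0.0571 each), called by camera at days 9 and 12, failed too. The actomyosin and death effector lists (0.0642 each) and the T cell list (0.101), also called at both days, did as well. Brush border genes fell in 22 of 27 members (22 when adjusted over the list alone; median -0.83, adjusted p = 1.43e-13, and adjusted p = 0.338 with an estimated correlation). Fetal-like and YAP target genes rose in 12 of 17 (13 when adjusted over the list alone; median 0.77, adjusted p = 1.64e-07, and adjusted p = 0.163 with an estimated correlation). The averaged call ended for B and plasma cell genes without WT day 6 replicate 2 (adjusted p = 0.116), KO day 9 replicate 2 (0.0688) or WT day 12 replicate 2 (0.0859), and for integrated stress genes without KO day 12 replicate 1 (0.0557) or WT day 12 replicate 2 (0.0542). It ended for fibroblast genes without WT day 6 replicate 2 (0.103), KO day 9 replicate 1 (0.0508), WT day 9 replicate 1 (0.0908), KO day 12 replicate 1 (0.0514) or WT day 12 replicate 2 (0.0539), and for visceral fat genes without WT day 6 replicate 2 (0.0506) or KO day 9 replicate 1 (0.0650). The smallest adjusted p with an estimated correlation was 0.163, in the p53 list at day 6 and the fetal-like list at days 9 and 12 and on average. Camera thus called 0 of the 148 list tests that way, with 2, 4, 6 and 5 lists at an unadjusted p under 0.05 at days 6, 9 and 12 and on average.

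Camera called 15, 17 and 21 lists at days 6, 9 and 12. The same test called 13 lists between WT mice of days 9 and 6 and 12 lists between WT mice of days 12 and 6, where limma called 12 genes and 1 gene, and 0 of these lists passed with an estimated correlation (smallest adjusted p = 0.539 and 0.402). The list calls at the preset correlation therefore also occur between groups of WT mice, with medians of up to 0.95 in size. With fry, which asks only whether a list moves one way, 2, 17 and 24 lists were called at days 6, 9 and 12 for KO against WT, and 0 between WT days. Fry does not set a list against the rest of the genes, and limma called 5917 and 5452 of 19938 genes at days 9 and 12. The lists fry called at those days thus need not have moved more than other genes. The lists that fry called at day 6 were the p53 and fatty acid oxidation lists, and the other 13 lists that camera called had fry adjusted p from 0.0516 to 0.583. On average over days fry called neither the B and plasma cell list (adjusted p = 0.194) nor the fibroblast list (adjusted p = 0.0731), both called by camera.

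The next question was whether the genotype effect changed with time. The interaction passed for 3685 genes, or 18.5%, with the smallest p in Anxa10 (adjusted p = 4.84e-08), Aoc1, Asah2, Aspa, Olfm4 and Slc23a1. Asah2, a neutral ceramidase of the brush border, had log2 differences of -0.08, -1.44 and -3.94 at days 6, 9 and 12, and Slc23a1, a vitamin C transporter, of -0.12, -4.19 and -5.13. From day 6 to day 12 the difference between KO and WT changed for 2623 genes, upward for 1124 and downward for 1499. Of 31 mitosis genes 30 moved downward (31 when adjusted over the list alone; median -1.24, adjusted p = 2.00e-24, and adjusted p = 0.329 with an estimated correlation). Of 30 DNA replication genes 22 did so (27 when adjusted over the list alone; median -0.89, adjusted p = 2.50e-19, and adjusted p = 0.329 with an estimated correlation). Of 26 interferon-stimulated genes 18 did so (22 when adjusted over the list alone; median -1.16, adjusted p = 1.34e-15, and adjusted p = 0.329 with an estimated correlation). Smooth muscle genes moved upward in 9 of 15 members (13 when adjusted over the list alone). The median was 1.71 (adjusted p = 8.05e-07, and adjusted p = 0.478 with an estimated correlation). In 10 genes the difference passed in opposite directions at days 6 and 12, among them Nox1 (1.64 and -2.22), Oasl2 (1.21 and -2.18), Oas3 (1.10 and -1.35) and Prc1 (0.66 and -0.68). The interaction count was 2191 without KO day 6 replicate 2, 2383 without KO day 6 replicate 1 and 2438 without WT day 9 replicate 2, and the count from day 6 to day 12 was 1619 without KO day 6 replicate 2; with the smooth muscle mean as a covariate the counts were 1768 and 837.

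**Figure D3:**
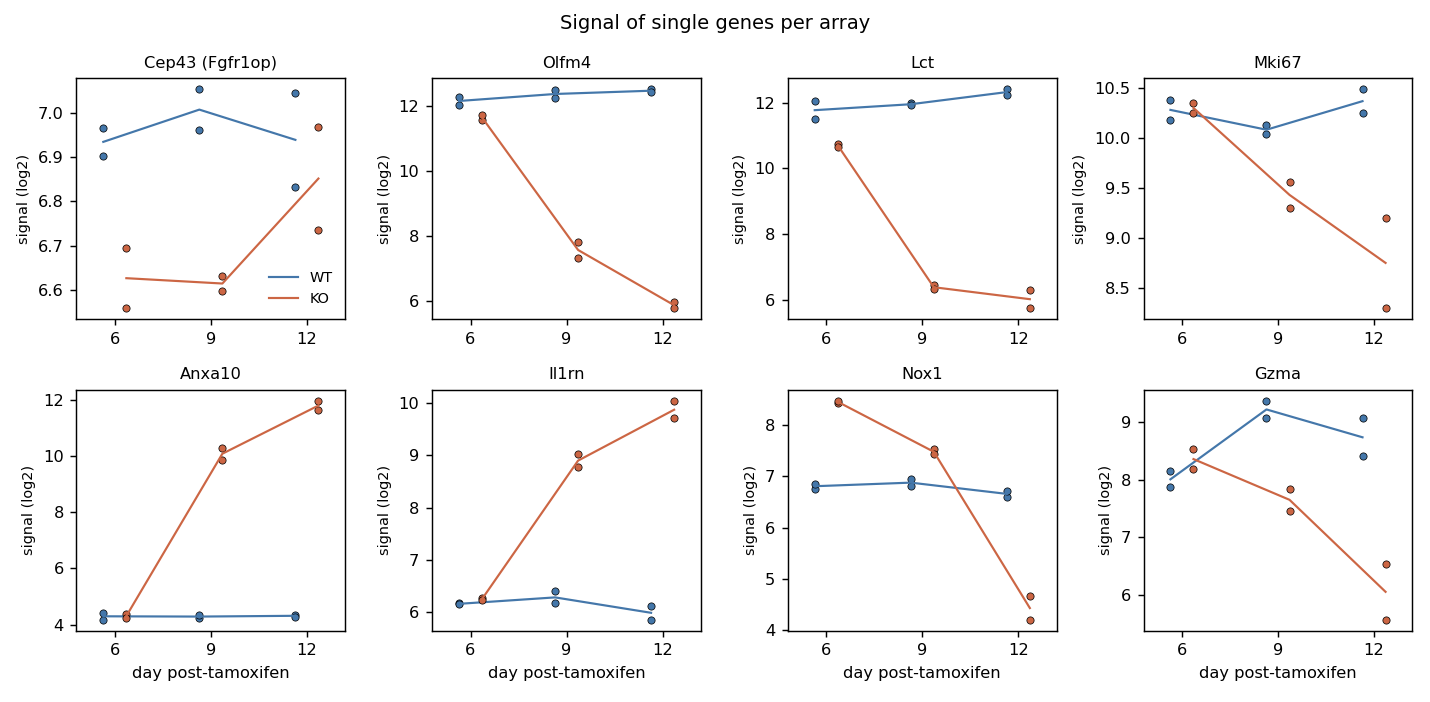
Log2 signal of 8 genes (y axis) per array by day after tamoxifen, 6 to 12 (x axis); points are single mice (2 per genotype and day), lines join group means, blue is WT and orange is KO. Cep43 lies at 6.60 and 6.63 in KO at day 9 and at 6.97 and 6.74 in KO at day 12, and the KO minus WT difference of Nox1 goes from 1.64 at day 6 to -2.22 at day 12.

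Genes called at day 6 were mostly called later too. Of 119 genes higher at day 6, 92 were higher at day 9, where independent lists of these sizes would share 15, and 88 at day 12 (independent lists, 16.3). Of 86 lower at day 6, 73 were lower at day 9 (independent lists, 14.7) and 72 at day 12 (independent lists, 11.8). Days 9 and 12 shared 1272 higher and 1884 lower genes (independent lists, 342.1 and 467). The fold changes of all genes correlated at a Pearson r of 0.394 between days 6 and 9, 0.338 between days 6 and 12 and 0.754 between days 9 and 12 (Spearman 0.257, 0.268 and 0.553), across genes, which are not independent replicates. The 3 days have separate WT mice. The 165 genes shared in direction by days 6 and 9 and the 160 shared by days 6 and 12 became 21 and 20 without KO day 6 replicate 2, 26 and 24 without KO replicate 1, 33 and 31 without WT replicate 1, and 99 and 90 without WT replicate 2 of that day. They became 79 to 81 and 76 without a WT array of day 9, and 96 and 88 to 91 without one of day 12.

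Over days within WT, limma's F test called 4 genes of 19938, with 2003 at an unadjusted p under 0.05. Slc10a2, the bile acid transporter, went from a mean log2 signal of 7.80 at day 6 to 6.72 at day 9 and 5.94 at day 12 (adjusted p = 0.0184). The KO minus WT difference of Slc10a2 at days 9 and 12 thus came with a fall in WT. The acute phase gene Saa1 had means of 3.68, 5.02 and 3.67, the kinase Pim1 9.28, 10.17 and 9.57, and the thyroid hormone deiodinase Dio1 8.15, 8.99 and 8.72 (adjusted p = 0.0465 each); the glucocorticoid target Fkbp5 (9.08, 7.88 and 8.84) did not pass (adjusted p = 0.105). The count was 0 without either KO array of day 9, 1 without WT day 12 replicate 2, 2 without either KO array of day 6 and 8 without either WT array of day 6. The call of Slc10a2 ended without either KO array of day 9 or without WT day 12 replicate 2. That of Dio1 ended without any single array, that of Pim1 without any but the KO arrays of day 12, and that of Saa1 without any but WT day 9 replicate 1. Within KO the same test called 7487 genes, with the smallest p in Anxa10 (adjusted p = 9.96e-10), Aoc1, Asah2 and Slc40a1.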

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

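The tests of muscle content and of the day 6 WT arrays, the test of a general loss of immune cells and the 3 tests on Cep43 were chosen only after the result was seen. The KO minus WT difference was itself tested between days, and 3685 genes passed the interaction test. From day 6 to day 12 the difference moved by a median of -1.24 for mitosis genes, -0.89 for DNA replication genes and -1.16 for interferon-stimulated genes. In 10 genes it passed in opposite directions at the 2 days, with the change between the days passing too: Nox1, Oasl2, Oas3, Usp18, Prc1, Cenpi, Ces1g and Igkv4-91 went from higher to lower, and Adgrg6 and Tnnt2 from lower to higher. Of 100 splits of the genotypes within days, drawn from 108 possible ones, 1, the real one, called as many genes for the average over days. Chance is thus an unlikely source of that count. The real split called 6493 genes and the highest other 5658. That other split exchanged the genotypes of day 6 alone and left days 9 and 12 intact, so the test says little about day 6. Among 13767 probe sets with several symbols or unnamed here, which the comparisons by gene leave out, 1139 passed for KO against WT at day 9 and 869 at day 12, against 2 at day 6 and 0 for WT mice between days 12 and 6.

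At day 6 the lists of mitosis, interferon-stimulated and p53 target genes stood higher in KO, in arrays with a lower smooth muscle signal. With the smooth muscle mean as a covariate the KO minus WT list mean was 0.228 for p53 targets (SE 0.052, from 0.251, SE 0.031). This argues against muscle content as the whole cause only if the slope within groups also holds between genotypes. The smooth muscle means of the genotypes did not overlap at day 6. In the p53 list both KO arrays lay at least 0.131 above the highest later WT array, which argues against low WT arrays as the whole cause. Low WT arrays may be part of it, since the day 6 WT arrays (7.534 and 7.563) lay below the later ones (7.619 to 7.665). Against the later WT arrays the difference was 0.163. For mitosis genes the KO arrays lay at least 0.164 above the later WT arrays, but the adjusted mean was 0.136 (SE 0.171, from 0.327, SE 0.117), so muscle content cannot be told apart from genotype: with 2 mice per group the smooth muscle signal follows genotype, and the covariate widened the error. For interferon-stimulated genes neither explanation can be told apart from genotype, with an adjusted mean of 0.292 (SE 0.255, from 0.473, SE 0.159) and a lower KO array that stood at -0.191 from the highest later WT array. A response of p53 targets to loss of the centrosome gene may stand behind the p53 list, as a hypothesis found and tested on the same data, but at day 9 the list stood at a median of -0.01 and was called by neither camera nor fry. At day 12 fry called it higher and camera did not call it. From day 9 to day 12 its KO minus WT difference moved up by a median of 0.191 (camera adjusted p = 0.00675, and adjusted p = 0.329 with an estimated correlation, fry adjusted p = 0.00216).

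At day 12 brush border and T cell lists stood lower in KO. A smaller share of epithelial RNA would lower epithelial genes alike, yet the median of 18 pan-epithelial genes was 0.075 (95% bootstrap interval -0.12 to 0.505), with Krt18 at 1.54 and Epcam at -0.22, against -1.37 for brush border genes. A general loss of immune cells would lower myeloid genes too, yet the macrophage and monocyte median was 0.397 (95% bootstrap interval 0.081 to 0.693). Both intervals resample the genes of a list, all measured in the same 2 mice per group, so the spread between mice is not in them. A change in the state of the epithelium and a loss of some lymphocytes may remain, as hypotheses; cell numbers were not measured in the data used here.

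Cep43 stood near its WT level in KO at day 12. A wrong label on these arrays is argued against by the other genes: of 1032 genes that changed at least 2-fold at day 9, 99.1% and 94.4% lay on the KO side in the 2 arrays. A return of epithelium that kept the gene would bring brush border and stem cell genes back towards WT, yet the median ratio of their day 12 to day 9 changes was 1.112 (95% bootstrap interval 0.812 to 1.35, 35 genes). That interval resamples genes and not mice. Spread between single arrays cannot be told apart from a real change, since the difference between days 9 and 12 was 0.304 (SE 0.154) with 2 mice per group. Signal from cells outside the epithelium and probes outside the deleted part were not tested.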

How the results depend on the processing

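Covariates for smooth muscle and for B and plasma cells were the tests chosen after seeing the data. Among other settings than leaving out arrays, values of named genes stayed on their side of the threshold in 813 cases, weakened in 56, strengthened in 2 and reversed in 0; lists did so in 1733, 125, 23 and 6. With 1 array left out, a lone array is assumed to vary like the other groups; the counts were 824, 76, 0 and 0 for genes and 1713, 33, 29 and 1 for lists. The number of arrays limits the precision. For the changes below the cause was not tested, except where a setting tests more probe sets or uses fewer arrays.

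At day 6 the count of 205 genes was 45 over all probe sets, 415 with array weights, 101 with the replicate block within day, 17 with the smooth muscle covariate and 383 at an adjusted p under 0.10. At 1.5-fold or more the counts were 2830, 2914 and 1470 at days 9 and 12 and on average. The smooth muscle covariate gave 837 genes from day 6 to day 12 and 1768 for the interaction. Limma's 4 genes over days in WT were 0 over all probe sets and with either replicate block, 1 with the dim filter, quantile normalisation, median centring and either covariate, and 10 with array weights; KO over days gave 4103 with the replicate block within day. Genes shared by days 6 and 9, and by days 6 and 12, were 42 and 39 over all probe sets, 310 and 297 with array weights, 85 and 83 with the replicate block and 16 and 13 with the smooth muscle covariate. Deviations of equal replicate numbers correlated at 0.18, -0.09 and 0.11 at days 6, 9 and 12. With 2 mice per group this gives 1 value per day, so it cannot exclude that the replicate numbers pair the mice.

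With an estimated correlation, camera called 0 lists at day 6, 0 at day 9, 0 at day 12 and 0 on average; fry called 2 at day 6. Fry ended 18 camera calls, those of all lists but p53 and fatty acid oxidation at day 6, of DNA replication and fibroblast at day 9, of B and plasma cell at day 12, and of B and plasma cell and fibroblast on average. Fry added 8: macrophage at day 9, enteric neuron at days 9 and 12, p53, integrated stress and Crohn's disease risk at day 12, and p53 and enteroendocrine on average. The dim filter ended 15 list calls: cholesterol, fetal-like and enteric neuron at day 6; stem cell, DNA replication, tuft cell, neutrophil and fibroblast at day 9; enteroendocrine, neutrophil and death effector at day 12; B and plasma cell, fibroblast, integrated stress and death effector on average. Quantile normalisation ended 4 (cholesterol and fetal-like at day 6, DNA replication at day 9, integrated stress on average). The smooth muscle covariate ended 5 (stem cell, centriole and tuft cell at day 6, death effector and visceral fat at day 12), and the B and plasma cell covariate 5 (fetal-like and B and plasma cell at day 6, enteroendocrine at day 12, fibroblast and integrated stress on average). Median centring, array weights and the replicate block over the series each ended the fetal-like call at day 6. The Crohn's disease risk list passed at day 12 with fry, the mean of a gene's probe sets, either replicate block and the arrays of day 12 alone. The last of these settings adjusted over 37 tests in place of 148. Lists that reversed had adjusted p = 0.126 (cholesterol), 0.975 (smooth muscle), 0.712 (enteric neuron) and 7.10e-04 (visceral fat) at day 6 with the smooth muscle covariate, 0.897 and 0.892 (B and plasma cell, day 12 and average) with its own covariate, and 0.723 (B and plasma cell, day 6) without WT day 6 replicate 2. Over the arrays left out, that day 6 list ranged from 4.03e-07 to 0.723.

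Leaving out each array in turn, counts ranged from 21 to 291 at day 6, 3646 to 6542 at day 9, 3740 to 5557 at day 12, 5541 to 7128 on average, 1619 to 3046 from day 6 to day 12, 2191 to 4667 for the interaction, 0 to 8 over days in WT and 5351 to 7962 in KO. Shared genes ranged from 21 to 230 (days 6 and 9), 20 to 217 (days 6 and 12) and 2378 to 3471 (days 9 and 12). Lists called ranged from 12 to 16, 16 to 18, 20 to 22 and 19 to 23 at days 6, 9, 12 and on average. Cep43 ranged from -0.37 to -0.24, -0.44 to -0.35, -0.20 to 0.03 and -0.30 to -0.22 in the same order.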

Other observations

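None of the tests in this part was chosen after its result was seen, but the lists were drawn up because single members had stood out. The list p-values of this part were adjusted over its own lists at days 9 and 12 alone. That family is smaller than the one of the lists above, so adjusted p-values of the 2 parts are not comparable. Targets of NRF2, the factor behind antioxidant genes, were higher in KO at day 12. Of 16 members, without Slc7a11 and Akr1b8, 7 rose and 0 fell: the haem oxygenase Hmox1 (log2 1.92, SE 0.13), the exporter Abcc1 (1.68, SE 0.15), the carbonyl reductase Cbr3 (1.66, SE 0.19) and the exporter Abcc4 (1.43, SE 0.11) were examples. The median was 0.265 (camera adjusted p = 2.75e-04, and adjusted p = 0.0774 with an estimated correlation). A candidate explanation is NRF2 target induction, for which the unadjusted p with an estimated correlation was 0.0464. At day 9 the median was 0.575, with 12 of 16 rising (adjusted p = 3.26e-05, and adjusted p = 0.0709 with an estimated correlation) and 2 falling, Osgin1 (-0.97, SE 0.11) and Gclm (-0.39, SE 0.11). Hypoxia and glycolysis genes had a median of 0.767 at day 9, with 12 of 18 rising and 1 falling, among them the lactate exporter Slc16a3 (1.92, SE 0.11) and Bnip3 (1.75, SE 0.15) (adjusted p = 2.32e-07, and adjusted p = 0.0227 with an estimated correlation). In the larger family, the p53 list at day 6 had an unadjusted camera p of 0.00205 with an estimated correlation, which became 0.163. The unadjusted p of the hypoxia list at day 9 was 0.00227 by the same test, so its 0.0227 reflects the smaller family. At day 12, the day fixed for this test, the median was 0.477, with 10 of 18 rising and 2 falling (adjusted p = 0.0125, and adjusted p = 0.0781 with an estimated correlation). The unadjusted p with an estimated correlation was 0.0547, which leaves induction at that day open; Ndrg1 rose (1.99, SE 0.18) and Pdk1 fell (-0.87, SE 0.12).

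Gastric epithelial genes had a median of 0.108 at day 12, with 6 of 18 rising and 0 falling (adjusted p = 0.00978, and adjusted p = 0.0709 with an estimated correlation): the transcription factor Onecut2 (2.44, SE 0.26), Psca (2.34, SE 0.10), the protease Ctse (1.24, SE 0.20), Capn8 (1.18, SE 0.09), Vsig1 (1.10, SE 0.17) and Tff1 (0.54, SE 0.18). A gain of some gastric genes may have occurred, with an unadjusted p of 0.0246 with an estimated correlation, but the mucins Muc5ac and Muc6, the gastrokines, Tff2 and the pepsinogen Pgc did not pass, so the median rests on small changes. At day 9 the list did not pass (median 0.156, adjusted p = 0.0612; 5 rose and 2 fell), and Ctse (-0.78, SE 0.20) and Sult1c2 (-0.71, SE 0.15) fell. Squamous and wound keratinocyte genes had a median of 0.134 at day 12 (adjusted p = 0.0612), which leaves their gain at that day open, with Serpinb5 at 2.09 (SE 0.16). At day 9 the median was 0.231, with 7 of 16 rising and 0 falling (adjusted p = 0.00226, and adjusted p = 0.0709 with an estimated correlation). Slc10a2, an ileal transporter, was higher in KO than in WT, where its signal fell over the days. A list of other ileal genes, drawn up for bile acid handling, had a median of -0.328 at day 12 (95% bootstrap interval -1.344 to 0.074). Of its 8 genes 4 fell and 0 rose (camera adjusted p = 0.00692, and adjusted p = 0.0709 with an estimated correlation). The falls were those of Slc51b (-2.15, SE 0.10), Slc51a (-0.55, SE 0.12), Amn (-1.31, SE 0.19) and Tcn2 (-1.34, SE 0.09). Amn and Tcn2 serve vitamin B12 uptake and transport, so the list does not describe bile acid handling alone. The list members Fgf15, Nr0b2 and Nr1h4 lay between -0.11 and 0.16 at day 12 (SEs 0.12 to 0.14). Fabp6 stood at 0.02 with an SE of 0.84, so its value says little. At day 9 the list median was -0.345, with 4 falling, Amn and Tcn2 among them, and a rise of Fgf15 (0.53, SE 0.14) (adjusted p = 0.0240, and adjusted p = 0.0866 with an estimated correlation). The interval at day 12, which resamples genes and not mice, reaches above 0, so a general fall of the list is not settled. With 0 of 8 members rising at day 12, the list gave no sign of a gain beside Slc10a2, although Fabp6 was too variable to tell.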
